A study of Mus musculus with 9 samples.

How the data were processed

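The data were 9 libraries of ribosome-depleted total RNA, made with the Ion Total RNA-Seq Kit V2 and sequenced on an Ion Proton with 3 libraries per chip, per the labels. Which libraries shared a chip is not given in the sources used here, so a difference between chips could not be separated from a difference between groups. The groups were A1G tumours (Math1-cre, A1G allele, Ptch1 heterozygous), Ptch1 tumours (Ptch1 heterozygous) and cerebellum from wild-type adult C57BL/6 mice, with 3 libraries each. Tumour animals were of mixed strain and control animals were C57BL/6, so strain and tissue coincide in part in the comparison with cerebellum.

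Per the submitters' processing notes, the genome build was mm10 and the aligner named was Bowtie 0.12.2, without a statement of which step it served. The gene annotation, further alignment steps and quantification tool are not stated. The deposited tables hold 1 line per gene and library. Per the file headers, the expected counts are raw fragments assigned by the authors to each gene without scaling, and 1147 to 1440 genes per library held a value that was not whole to within 1e-06. The deposited signal columns are those fragments multiplied by the authors by 1 scaling factor per library, in a pair of columns that were equal in every line. The deposited FPKM values are scaled fragments per kilobase and per-million as computed by the authors. Scaling factors recomputed by median of ratios matched the deposited ones within 0.687%, for the tumours over the 6 tumour libraries and for cerebellum over the Ptch1 tumour and cerebellum libraries, a set that did not match for the Ptch1 tumours (0.968, 0.465 and 1.64 against deposited 0.813, 0.388 and 1.37). The deposited tumour and cerebellum values therefore came from separate scalings. Per scaled fragment the FPKM of cerebellum was 0.808 of that of tumours (log2 -0.31). The scaling factors act the other way, since factors over all 9 libraries differed from the deposited ones by a median log2 of -0.21 in cerebellum and 0.03 in tumours. From 0 to 4 genes per library carried a failed status and were kept at their listed values.

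Fragments were rounded to whole numbers and tested as counts. The plan written before the data were examined expected FPKM alone and named limma on log2(FPKM + 1). Since the tables hold fragments, edgeR's quasi-likelihood test on counts became the main test and the planned one an alternative. Genes with FPKM of at least 1 in at least 3 libraries were kept, which left 14337. The fit used edgeR 4.0.16 with TMM scaling and 1 mean per group over all 9 libraries, and contrasts compared A1G with Ptch1 tumours, the mean of the tumour groups with cerebellum, and each tumour kind with cerebellum. P-values were adjusted by Benjamini-Hochberg over all tested genes of a contrast, with 0.05 as threshold. Single genes were also tested by an exact two-sided permutation test of the group means, whose smallest p is 0.1 for 3 against 3 libraries. Other tools were limma 3.58.1 and DESeq2 1.42.0 under R 4.3.3, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Coordinates and gene types came from GENCODE M21 on mm10, matched by symbol for 21736 genes. Genes without a match have no coordinates in the text.

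The depth ranged from 2350941 to 9290237 fragments per library. A gene without a fragment in a library was taken to lie under a floor of 3 fragments, which is 1.28 CPM in the shallowest library and 0.323 CPM in the deepest. Folds against a group without fragments are lower bounds computed from the floor. Replicates of a group had Spearman correlations across genes of 0.887 to 0.968, and every replicate pair differed by more than sampling noise (chi-square per degree of freedom 10.9 to 43.5).

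A total of 34 gene lists was fixed before the data were examined, and 32 had tested members. Each was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other genes. It was repeated with an estimated correlation, and limma's fry tested whether the genes of a list moved on balance in 1 direction. Genes named in the text follow a rule written before the data were examined. Atoh1, Ptch1 and other Hedgehog pathway genes, among them Gli1, Gli2 and Mycn, were chosen whatever their values. Between A1G and Ptch1 tumours, the rule took up to 12 of the largest changes in each direction among genes past the threshold, without overlap between groups and with a mean FPKM of at least 2 in the higher group, and where fewer than 5 qualified, the 5 with the smallest p. Against cerebellum it took the 10 largest in each direction, of 2220 higher and 2401 lower genes that qualified. Predicted genes and small RNA genes known by a number or code were passed over. For each list the rule took 2 to 4 members with the largest changes past the threshold, or where none passed, 2 of the most abundant. List members that passed adjusted over the list alone, or that moved against their list, were named beyond the rule after their values were seen. Genes named per library in the closing section, such as Xist, Trp53, Cdkn2a, Bmp5 and Foxf2, were chosen after their values were seen.

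The main procedure was tested on simulated data with 200 changed genes spread over 2-fold, 4-fold and 8-fold changes. The changed genes were drawn from those at a mean of 10 CPM or more over all 9 libraries, so recovery below that level was not measured. That mean was the starting level of every group. Genes low in tumours and high in cerebellum were therefore simulated above their tumour level. Between A1G and Ptch1 tumours 7.46%, 61.2% and 93.9% of these were recovered with 9 false calls (7.69% of calls). Against cerebellum 11.9%, 88.1% and 100% were recovered with 14 false calls (9.52% of calls). Shared controls were simulated 20 times without effect. The cerebellum group of 3 libraries is too small to be split between the comparisons, so part of the common change may come from its shared libraries. Replicate numbers were checked for pairing. The correlation of libraries with the same number ranged from -0.07 to 0.21 and passed 0.1 in 3 of 9 pairs. Libraries of other groups with different numbers gave a wider range, from -0.25 to 0.24. Of the 9 libraries, 5 correlated best with one of their own number. The libraries were treated as unpaired, though a factor shared by number was not excluded.

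Each count of genes was recomputed under 23 alternatives, 18 planned as alternatives and 5 added later, among them the test first planned as the main one. Planned ones were no filter, a filter at FPKM 5, median-of-ratios scaling, a fit of only the groups compared, a replicate block, no dispersion trend, limma on log2(FPKM + 0.1) and on quantile-normalized log2(FPKM + 1), voom with array weights, and leaving out each library. Added after seeing the data were DESeq2, edgeR's own count filter, the robust quasi-likelihood test and protein-coding genes only. The other added one was limma on log2(FPKM + 1) as first written, which had been planned as the main test. For the gene lists against cerebellum, median-of-ratios scaling was also added. The largest shift of the median of all genes by a scaling was 0.06 (log2). DESeq2 gave no adjusted p for 1703 genes between A1G and Ptch1 tumours. Reads, alleles, splicing and the transgene itself were not analysed here. Chromosome shifts were corrected for transcript length, GC content and expression level by running medians over 40 bins, where a loess curve had been written down beforehand.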

Results

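RNA abundance was measured in 9 mouse libraries of ribosome-depleted total RNA, 3 from A1G tumours, 3 from Ptch1 tumours and 3 from wild-type adult cerebellum. A1G tumours arose in animals carrying Math1-cre, the A1G allele and 1 disrupted copy of the Hedgehog receptor gene Ptch1, and Ptch1 tumours in animals with the Ptch1 mutation alone. The A1G libraries held 2579173, 3049987 and 2350941 fragments assigned to genes, the Ptch1 libraries 4395159, 9290237 and 2699234, and the cerebellum libraries 3868432, 3304042 and 5300936. Of the listed genes, 14337 were expressed highly enough to be tested. Levels are given as normalised counts-per-million (CPM), mean ± SD over the libraries of a group (n = 3 unless stated). Log2 fold changes carry their standard error (SE), and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes. These p-values measure the spread between libraries, which the labels call replicates without saying whether each came from a separate animal. Lower bounds on folds set the mean of the group with fragments against the floor of the other. They allow for counting error in the group without fragments only, not for the spread between libraries. The values carry no strand information, and near-identical genes such as histones, ribosomal protein genes and globins share reads.

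The first comparison asked how strongly the gene behind the A1G model and the Hedgehog pathway were expressed in each tumour kind. Atoh1, the transcription factor that keeps granule neuron progenitors dividing (chromosome 6, 64729125 to 64731245, mm10), stood at 445 ± 185 CPM in A1G tumours, 337 ± 63.4 CPM in Ptch1 tumours and 8.80 ± 8.26 CPM in cerebellum. It was higher in the tumours than in cerebellum by 5.43 on the log2 scale (SE 0.82, adjusted p = 2.15e-04), and by 4.86 to 6.31 when 1 library was left out, lowest without cerebellum replicate 1 and highest without cerebellum replicate 3. A1G and Ptch1 tumours overlapped in Atoh1, with a log2 difference of 0.40 (SE 0.69, adjusted p = 0.876). Reads from a transgene and from the endogenous gene could not be separated in these values. Ptch1 (chromosome 13, 63508328 to 63573598) stood at 146 ± 133 CPM in A1G tumours, 75.0 ± 23.7 CPM in Ptch1 tumours and 114 ± 62.9 CPM in cerebellum. The A1G mean rested on replicate 2 (299.7 CPM), since replicates 1 and 3 were at 79.6 and 60.04 CPM, within the 52.8 to 99.996 CPM of the Ptch1 tumours. No difference in Ptch1 passed the test between the tumour kinds (adjusted p = 0.560) or between tumours and cerebellum (adjusted p = 0.858), and counts per gene do not separate the mutant from the intact allele.

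Of 17 Hedgehog pathway genes, 14 were higher and 2, Cdon and Spop, lower in tumours, and the list passed at camera's preset correlation (adjusted p = 2.4e-09) but not with an estimated correlation (adjusted p = 0.126). Gli1, the transcription factor switched on by active Hedgehog signalling (chromosome 10, 127329882 to 127341974), stood at 149 ± 39.6 CPM in A1G tumours, 196 ± 10.1 CPM in Ptch1 tumours and 11.9 ± 3.40 CPM in cerebellum, a log2 change of 3.84 (SE 0.31, adjusted p = 1.91e-06). Gli2, a second effector of the pathway (chromosome 1, 118834132 to 119053619), rose by 4.14 (SE 0.37) from 8.25 CPM in cerebellum. Mycn, which drives progenitor growth (chromosome 12, 12936093 to 12941914), was at 426 ± 80.1 CPM in A1G tumours and 496 ± 42.8 CPM in Ptch1 tumours against 8.64 ± 1.52 CPM in cerebellum, a log2 change of 5.72 (SE 0.30, adjusted p = 1.5e-07). None of Gli1, Gli2 and Mycn differed between A1G and Ptch1 tumours past the test. Gli1 was lower in every A1G library than in any Ptch1 library (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow, adjusted p = 0.642).

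**Figure D1:**
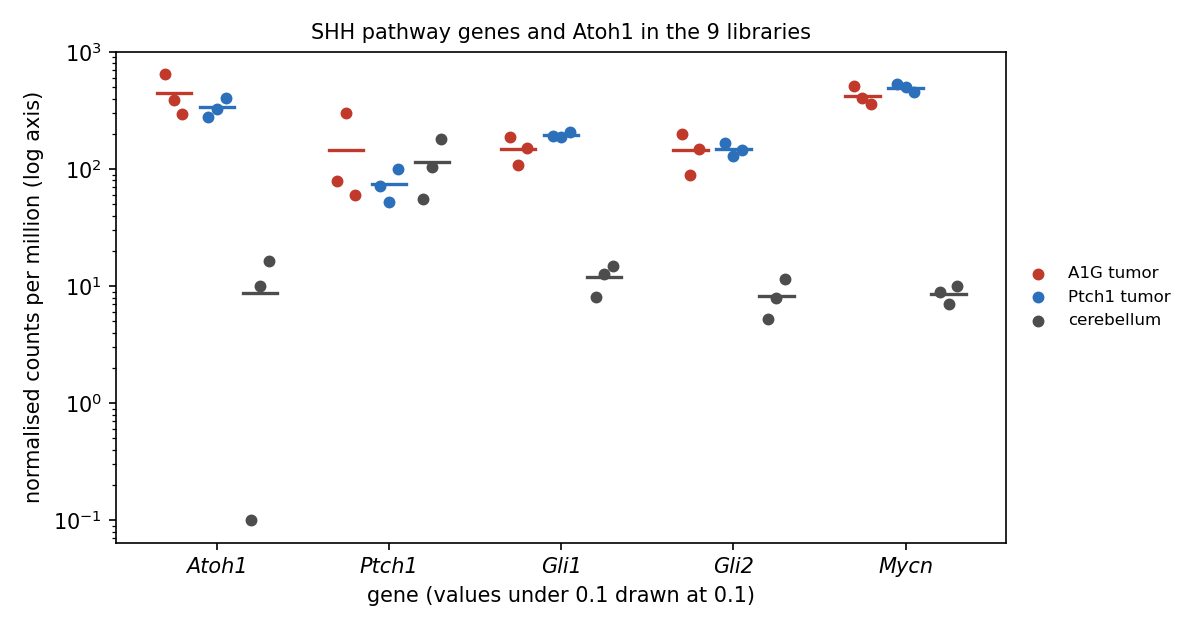
Normalised counts-per-million (CPM, log axis) of Atoh1, Ptch1, Gli1, Gli2 and Mycn, with 1 point per library, lines at the group means, and values under 0.1 drawn at 0.1. Atoh1, Gli1, Gli2 and Mycn were higher in all 6 tumour libraries than in any cerebellum library, while the 3 groups overlapped in Ptch1.

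The central question of the design was what sets A1G tumours apart from Ptch1 tumours. Only 2 of 14337 genes passed edgeR's test, and both were higher in A1G tumours. Calb1, a calcium-binding protein abundant in Purkinje cells (chromosome 4, 15881264 to 15908064), was at 17.3 ± 5.79 CPM in A1G and 1.20 ± 0.558 CPM in Ptch1 tumours, a log2 difference of 3.81 (SE 0.40, adjusted p = 0.00627). Arhgef33, a guanine nucleotide exchange factor (chromosome 17, 80307407 to 80400081), was at 14.8 ± 5.83 CPM and 0.529 ± 0.470 CPM, a difference of 4.42 (SE 0.53, adjusted p = 0.0151). Cerebellum held far more of either transcript, 673 ± 109 CPM of Calb1 and 398 ± 88.8 CPM of Arhgef33. Leaving out Ptch1 replicate 2 ended both calls (adjusted p = 0.110 for each), and leaving out Ptch1 replicate 1 ended that of Arhgef33 (adjusted p = 0.0709). At an unadjusted p under 0.05 edgeR counted 1525 genes, and the 3 libraries of one kind did not overlap those of the other in 15.5% of genes, where chance gives 10%. DESeq2 called 163 genes on the same counts, 107 higher and 56 lower in A1G tumours. Limma on log2(FPKM + 1), the test first planned as the main one, called 0 genes, with 1391 at an unadjusted p under 0.05.

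Of 72 further named genes that did not pass the test, 11 passed in some alternative. Rasgrf1, a neuronal activator of Ras (chromosome 9, 89909908 to 90026977), was at 11.3 CPM in A1G and 1.11 CPM in Ptch1 tumours (log2 3.17, SE 0.44, adjusted p = 0.0501), with 250.5 CPM in cerebellum, and it passed in 7 alternatives, among them median-of-ratios scaling (adjusted p = 0.0441), the stricter filter (0.0450) and the fit without A1G replicate 2 (0.00901). Pcdh7, a protocadherin for cell adhesion (chromosome 5, 57717967 to 58133230), was at 96.3 ± 74.9 CPM in A1G tumours, 7.12 ± 4.198 CPM in Ptch1 tumours and 67.9 ± 5.18 CPM in cerebellum (log2 3.72, adjusted p = 0.0702), and it passed in 4, including without A1G replicate 1 (0.0498) or replicate 3 (0.0433). Sema5a, an axon guidance cue (chromosome 15, 32244810 to 32696341), was at 28.3 CPM against 4.86 CPM in Ptch1 tumours (log2 2.54, adjusted p = 0.1003), and it passed without a filter (0.00262) and with DESeq2 (1.2e-05). In the other direction the smallest p-values belonged to Fabp5, a fatty acid carrier (chromosome 3, 10012548 to 10016607), Rpph1, the RNA of the enzyme that trims transfer RNAs (chromosome 14, 50807449 to 50807767), Pnn, a splicing-associated protein (chromosome 12, 59066884 to 59073998), Tgoln2 of the Golgi network and Fkbp2 of the endoplasmic reticulum (chromosome 19, 6977741 to 6980501). Their log2 differences were -1.62, -1.39, -1.21, -1.61 and -1.58, with adjusted p from 0.217 to 0.265, while all 5 passed with DESeq2 (adjusted p from 7.6e-06 to 0.00542), and Fabp5, Tgoln2 and Fkbp2 also without a filter (0.0173, 0.0217 and 0.0422). Rpph1, the most abundant of them, was at 3489 ± 289 CPM in A1G and 9124 ± 1239 CPM in Ptch1 tumours. With 3 libraries per kind, a test on simulated counts recovered 7.46% of 2-fold, 61.2% of 4-fold and 93.9% of 8-fold changes in genes at 10 CPM or more, so small differences were rarely detected. The simulated levels were means over all 9 libraries, cerebellum included. Recovery was not measured at the tumour levels of genes that are low in tumours and high in cerebellum.

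**Figure D2:**
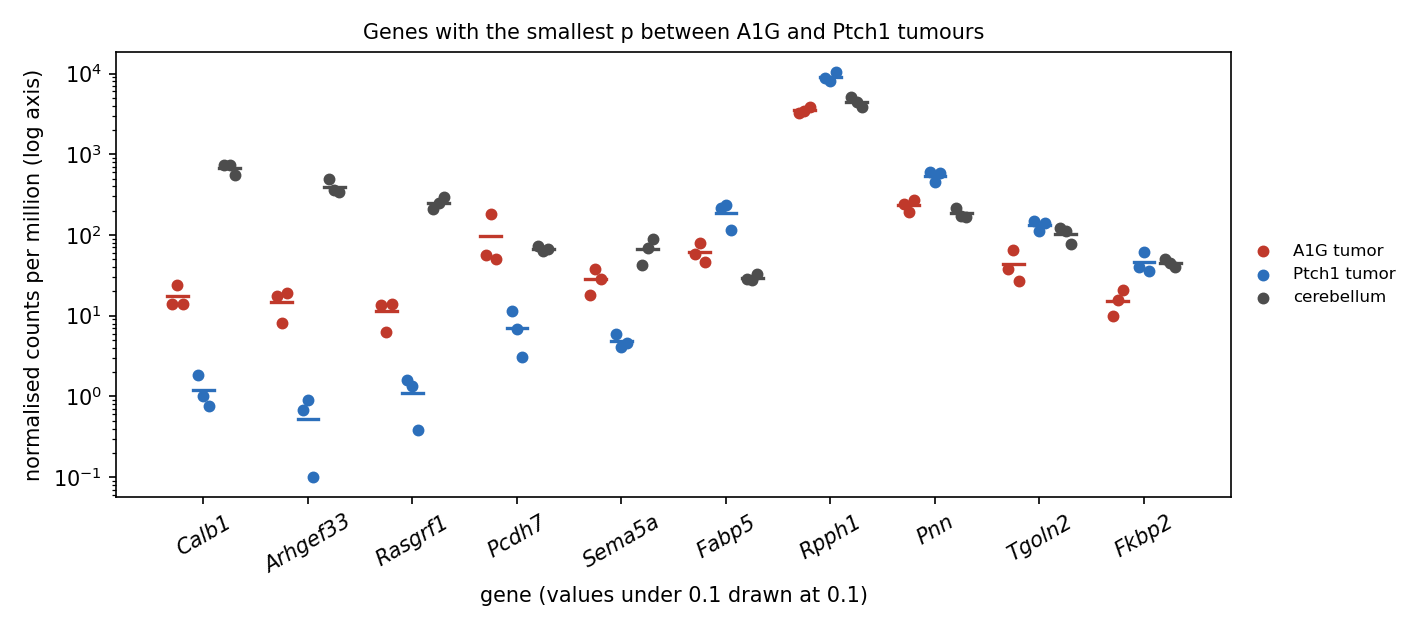
Normalised counts-per-million (CPM, log axis) of the 5 genes with the smallest p in each direction between A1G and Ptch1 tumours, with 1 point per library, lines at the group means, and values under 0.1 drawn at 0.1. The 3 A1G libraries lay apart from the 3 Ptch1 libraries in each of these 10 genes, of which Calb1 and Arhgef33 passed the test.

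A related question was whether cell types or processes shifted together between the tumour kinds, which was asked of 34 gene lists fixed beforehand. Camera with its preset correlation called 9 of the 32 lists that had tested members, and 0 lists passed with an estimated correlation or by limma's fry. Of 40 cell cycle genes, 37 had lower fitted levels in A1G tumours (median log2 -0.52, camera adjusted p = 2.2e-07, adjusted p = 0.548 with an estimated correlation), and 0 genes passed edgeR's test, whether adjusted over all genes or adjusted over the list alone. The libraries overlapped, with list means of log2(CPM + 1) of 6.77, 5.88 and 6.30 in A1G replicates 1 to 3 and of 6.72, 7.14 and 6.68 in the Ptch1 replicates. Mki67, the proliferation antigen, was at 2231 ± 1462 CPM in A1G and 3764 ± 287 CPM in Ptch1 tumours, with 620 CPM in A1G replicate 2 alone, and Top2a, the topoisomerase of dividing cells, at 412 ± 126 and 751 ± 238 CPM. Of 46 replication-dependent histone genes, 44 were lower (median -0.45, adjusted p = 1.8e-09, adjusted p = 0.548 with an estimated correlation), and 0 passed over all genes while 8 fell in A1G tumours adjusted over the list alone. Hist1h4d was at -0.39 and Hist1h2bb at -0.86, and among the 8 were the neighbours Hist1h2af (-1.04) and Hist1h2ag (-1.04), whose near-identical sequences share reads. Of 74 cytosolic ribosomal protein genes, 57 were lower (median -0.23, adjusted p = 0.00129, adjusted p = 0.873 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone, with Rpl4 at -0.79 and Rplp1 at 0.07. Without Ptch1 replicate 2 the ribosomal median was -0.08 (adjusted p = 0.277) and the histone median -0.30 (adjusted p = 9.7e-06), and without A1G replicate 3 the ribosomal adjusted p was 0.0587. At an unadjusted p under 0.05 edgeR counted 7 cell cycle, 12 histone and 6 ribosomal protein genes. Among all 14337 tested genes it counted 1525, a larger share than that of the ribosomal protein genes.

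Markers of mature cerebellar cells leaned the opposite way at the preset correlation, from low levels. Of 20 Purkinje cell markers, 16 were higher in A1G than in Ptch1 tumours (median log2 1.18, camera adjusted p = 1.4e-10, adjusted p = 0.183 with an estimated correlation). Calb1 alone rose over all genes and 9 rose adjusted over the list alone, among them Car8 (33.4 against 3.50 CPM, 1446 CPM in cerebellum) and Itpr1, the calcium channel of Purkinje cell stores (421 against 189 CPM, 5892 CPM in cerebellum). Of 17 oligodendrocyte markers, 14 were higher (median 1.11, adjusted p = 2.0e-07, adjusted p = 0.183 with an estimated correlation), and 0 passed over all genes while the myelin genes Mog, Cnp and Cldn11 made up 3 adjusted over the list alone. Mbp, the main myelin protein gene, stood at 223 ± 31.2 against 141 ± 112 CPM, with 4454 CPM in cerebellum. Of 13 inhibitory interneuron markers, 9 were higher and 3 lower (median 0.64, adjusted p = 4.8e-04, adjusted p = 0.183 with an estimated correlation), with 0 over all genes and 3 adjusted over the list alone. Gad1, which makes GABA, stood at 18.4 ± 16.7 against 1.15 ± 1.06 CPM. The interneuron median was 1.17 without Ptch1 replicate 2 and 1.15 without Ptch1 replicate 3. Of 22 mature granule neuron genes, 18 were higher (median 1.02, adjusted p = 4.8e-06, adjusted p = 0.629 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone, with Snap25 at 0.53 and Cbln1 at 1.05. That median was 0.55 without A1G replicate 3, 0.61 without Ptch1 replicate 2 and 1.72 without Ptch1 replicate 3. At an unadjusted p under 0.05 edgeR counted 11 Purkinje, 6 oligodendrocyte, 5 interneuron and 5 mature granule neuron genes. The count over all 14337 tested genes was 1525.

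Glial lists passed narrowly. Astrocyte and Bergmann glia markers had a median of 0.14 (12 of 20 higher, adjusted p = 0.0327, adjusted p = 0.698 with an estimated correlation), with 0 over all genes and Gdf10, Slc4a4 and Ntsr2 as the 3 adjusted over the list alone. Their call ended without A1G replicate 1 (adjusted p = 0.0707), A1G replicate 3 (0.127), Ptch1 replicate 1 (0.165) or Ptch1 replicate 3 (0.684). The median turned to -0.06 in the last pair while the test stayed upward, and it was 0.89 without Ptch1 replicate 2. Oligodendrocyte precursor markers, such as Pdgfra (-0.64) and C1ql1 (0.59), had a median of 0.60 (10 of 13 higher, adjusted p = 0.0465, adjusted p = 0.548 with an estimated correlation), with 0 over all genes or adjusted over the list alone. Their call ended without A1G replicate 1 (adjusted p = 0.231), Ptch1 replicate 2 (0.0785), Ptch1 replicate 3 (0.286) or cerebellum replicate 3 (0.0536). At an unadjusted p under 0.05 edgeR counted 6 astrocyte and 2 precursor markers, and 1525 of all 14337 tested genes.

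The other 23 tested lists were not called between the tumour kinds in the full fit, and 8 of them were called at the preset correlation when 1 library was left out. Endothelial markers were called in 4 such fits (without A1G replicate 2 or 3, or Ptch1 replicate 2 or 3), mesenchymal transition genes in 3, microglia and macrophage markers and pericytes in 2 each, and meningeal fibroblast, Notch and Hedgehog genes and abundant non-polyadenylated RNAs in 1 each. In all, 13 lists were called without A1G replicate 2 and 12 without Ptch1 replicate 2. The values that follow are of the full fit. Hedgehog pathway genes had a median of -0.33 (adjusted p = 0.292, 5 of 17 higher), and Cdon, a coreceptor for Hedgehog ligands, was the 1 member that rose adjusted over the list alone (9.48 against 1.06 CPM, 67.8 CPM in cerebellum). Granule neuron progenitor genes (median 0.19, adjusted p = 0.821) and immature granule neuron genes (0.11, 0.947) were not called as lists. Among tissue compartments, the adjusted p was 0.222 for microglia and macrophages, 0.0503 for endothelium, 0.292 for pericytes and smooth muscle, 0.314 for meningeal fibroblasts, 0.908 for T and NK cells, 0.821 for erythrocytes, and 0.865 for neutrophils, choroid plexus and ependymal cells alike. Extracellular matrix genes (median 0.11, adjusted p = 0.234) and genes of mesenchymal transition and invasion (0.24, 0.109) did not pass either. Nor did Notch pathway genes (adjusted p = 0.378), WNT targets (0.925), p53 targets (0.222), interferon-stimulated genes (0.865), immediate early and heat shock genes (0.925), or hypoxia genes (0.844). The glycolysis genes (0.865) had a median of 0.02 with a mean of -0.01 and a downward test. The abundant non-polyadenylated RNAs (0.378), of which Rpph1 fell adjusted over the list alone, had a median of 0.27 with a mean of -0.03 and a downward test. For the sex-linked genes (0.865) the median was -0.97 and the mean 0.46, and Xist was the 1 member that rose adjusted over the list alone. The mitochondrially encoded list and the hindbrain Hox list had 0 tested members.

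The next comparison asked how the 6 tumours differed from normal adult cerebellum. Of 14337 genes, 2962 were higher and 3082 lower in tumours, and 5022 of the 6044 changed by 2-fold or more. Groups did not overlap for 38.2% of all genes, where chance gives 2.38% for 6 libraries against 3. Nhlh1, a transcription factor of newborn neurons (chromosome 1, 172052292 to 172057573), was at 120 ± 90.9 CPM in tumours (n = 6) and had no fragment in cerebellum, at least 156-fold higher against a floor of 3 fragments per library. By the same floor Kntc1 of the kinetochore (chromosome 5, 123749716 to 123821593) was at least 140.2-fold higher, the DNA helicase gene Pif1 (chromosome 9, 65587160 to 65595967) 81.2-fold, Shcbp1 (chromosome 8, 4735976 to 4779567) 42.1-fold, and the mitotic kinase gene Pbk (chromosome 14, 65805837 to 65817822) 36.1-fold. The cohesion factor gene Cdca5 (chromosome 19, 6084983 to 6091777) was at least 32.8-fold and the homeobox gene Lhx2 (chromosome 2, 38339281 to 38369733) at least 24.8-fold higher. Draxin, an axon guidance protein (chromosome 4, 148098437 to 148130698), was at 725 ± 240 CPM against 1.06 ± 0.487 CPM, a log2 change of 9.36 (SE 0.56, adjusted p = 2.9e-07). Uhrf1, which maintains DNA methylation in dividing cells (chromosome 17, 56303321 to 56323486), was at 259 ± 79.7 CPM against 0.308 ± 0.274 CPM (log2 9.48, SE 0.53), and Igfbpl1 (chromosome 4, 45809468 to 45826923) at 166 ± 28.3 CPM against 2 fragments in cerebellum.

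The genes named for the largest decreases in tumours were of several kinds. Hbb-b1, a beta-globin, was at 41.0 ± 14.7 CPM in cerebellum and had no fragment in tumours, at least 45.2-fold lower. By the same floor the glycine transporter gene Slc6a5 (chromosome 7, 49910146 to 49963856) was at least 13.1-fold lower, the myelin gene Opalin (chromosome 19, 41061710 to 41077113) 10.2-fold, the desmosome gene Pkp3 (chromosome 7, 141078218 to 141090510) 8.72-fold and the muscle gene Smpx (chromosome X, 157698910 to 157752591) 8.20-fold. Pcp2, a Purkinje cell protein (chromosome 8, 3623371 to 3625545), fell from 226 ± 89.2 to 0.785 ± 1.30 CPM (log2 -10.03, SE 0.56, adjusted p = 6.9e-07). Ppp1r1b, a neuronal phosphatase inhibitor (chromosome 11, 98348404 to 98357796), fell from 108 ± 39.4 to 0.497 ± 0.313 CPM (log2 -7.96, SE 0.42). Dao, which degrades D-amino acids (chromosome 5, 114003703 to 114025682), fell from 102 ± 24.2 to 0.142 CPM (3 fragments), and the keratin gene Krt25 (chromosome 11, 99315516 to 99322951) from 14.0 ± 5.18 to 0.0187 CPM (1 fragment). Ttr, the transport protein of choroid plexus (chromosome 18, 20665280 to 20674321), rested on cerebellum replicate 1, at 2678 CPM against 37.7 and 83.5 CPM in the other cerebellum libraries. Its log2 change went from -9.12 to -5.13 without that library, and that of Smpx from -7.91 to -6.61.

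At camera's preset correlation, lists of dividing progenitor genes rose in tumours together with ribosomal and microglial genes. Of 40 cell cycle genes, 38 were higher and 0 lower, with 39 higher adjusted over the list alone (median log2 5.67, camera adjusted p = 1.2e-45, adjusted p = 0.0492 with an estimated correlation). Mki67 stood at 2997 ± 1262 CPM (n = 6) against 5.54 ± 1.75 CPM, a log2 change of 9.04, beside Aurkb (8.58), Ccnb1 (8.51) and Cenpf (8.42). All 46 tested histone genes were higher, adjusted over all genes and adjusted over the list alone (median 5.04, adjusted p = 3.3e-63, adjusted p = 0.0200 with an estimated correlation), with Hist1h2bm at 7.67 and Hist1h3c at 6.68. Of 17 Hedgehog pathway genes, 14 were higher and 2 lower by either adjustment, including adjusted over the list alone (median 2.57, adjusted p = 2.4e-09, adjusted p = 0.126 with an estimated correlation). The highest were Sfrp1 (7.49), Ccnd2, a cyclin of progenitor division (7.09), and Mycn, and the lower ones were Cdon (-4.32) and Spop (-1.77). Of 17 granule neuron progenitor genes, 9 were higher and 2 lower, the same counts adjusted over the list alone (median 1.20, adjusted p = 0.00202, adjusted p = 0.223 with an estimated correlation), with Insm1 at 6.93 and Barhl1 at 4.26. Of 74 ribosomal protein genes, 66 were higher and 0 lower, with 69 higher adjusted over the list alone (median 1.77, adjusted p = 1.5e-15, adjusted p = 0.203 with an estimated correlation), such as Rps28 (2.84) and Rps2 (2.80). Of 26 microglia and macrophage markers, 14 were higher and 0 lower, with 15 higher and 1 lower adjusted over the list alone (median 1.56, adjusted p = 0.00319, adjusted p = 0.472 with an estimated correlation). These included Aif1 (4.34), the lysozyme gene Lyz2 (4.30) and Cd68 (2.69).

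At the preset correlation, lists of mature neurons, glia and vessels fell in tumours. Of 20 Purkinje cell markers, 19 were lower and 0 higher, also adjusted over the list alone (median log2 -5.23, camera adjusted p = 4.8e-27, adjusted p = 0.0184 with an estimated correlation), with Nefh at -7.63 and Car8 at -7.07. Of 17 oligodendrocyte markers, 16 were lower, also adjusted over the list alone (median -4.65, adjusted p = 3.2e-21, adjusted p = 0.0200 with an estimated correlation), including Mobp (-7.57) and Mal (-5.99). Of 13 interneuron markers, 10 were lower, and 11 adjusted over the list alone (median -2.95, adjusted p = 2.0e-09, adjusted p = 0.0200 with an estimated correlation), including Slc32a1 (-7.53) and Gad1 (-6.03). Of 22 mature granule neuron genes, 20 were lower, and 21 adjusted over the list alone (median -3.40, adjusted p = 4.6e-11, adjusted p = 0.203 with an estimated correlation), such as the GABA receptor genes Gabra6 (-5.98) and Gabrd (-5.55). Of 20 astrocyte and Bergmann glia markers, 16 were lower and Sox9 (1.43) was higher, the same counts adjusted over the list alone (median -3.07, adjusted p = 7.8e-11, adjusted p = 0.0658 with an estimated correlation), with Gdf10 at -6.15. Of 17 glycolysis genes, 12 were lower and 1 higher, also adjusted over the list alone (median -1.01, adjusted p = 6.9e-04, adjusted p = 0.259 with an estimated correlation). Aldoc (-5.70) and the neuronal enolase gene Eno2 (-4.25) fell, while the hexokinase gene Hk2 rose (3.81). Of 20 endothelial markers, 10 were lower, and 11 adjusted over the list alone (median -1.13, adjusted p = 0.00676, adjusted p = 0.259 with an estimated correlation), such as Ly6a (-3.07) and Tek (-2.23).

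**Figure D3:**
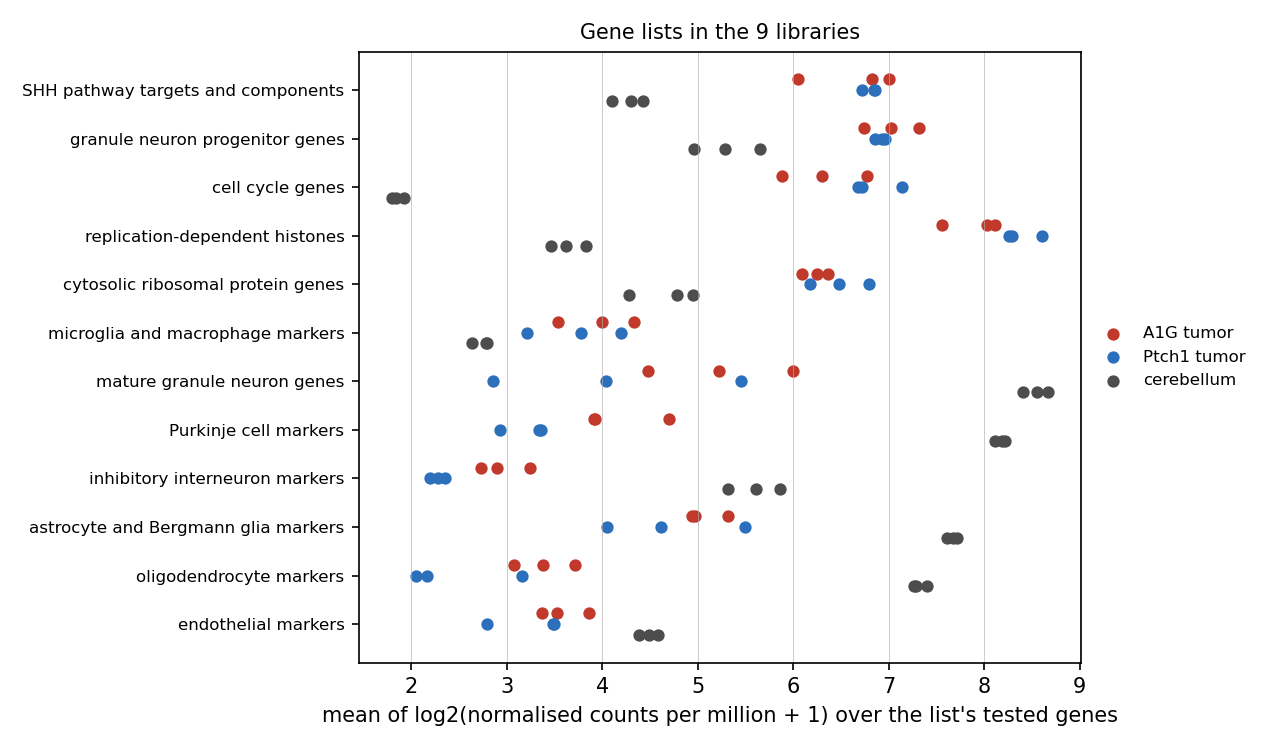
Mean of log2(normalised counts-per-million + 1) over the tested genes of 12 lists, with 1 point per library. In tumours the cell cycle, histone, Hedgehog, progenitor, ribosomal and microglial lists lay above cerebellum and the 6 lists below them in the plot lay under it.

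The remaining 19 tested lists did not pass against cerebellum. Immature granule neuron genes went both ways (4 higher, 2 lower of 19, adjusted p = 0.533), with a median of -0.11 but a mean of 0.33 and an upward test, and the neuronal migration gene Dcx was among those that rose (5.19). Mesenchymal transition and invasion genes had 13 higher and 5 lower of 35 (median 0.96, adjusted p = 0.0720), including the chemokine receptor gene Cxcr4 (6.60), and extracellular matrix genes 11 higher and 6 lower of 38 (adjusted p = 0.423). The invasion list passed without A1G replicate 3 (adjusted p = 0.0457), Ptch1 replicate 2 (0.0462) or Ptch1 replicate 3 (0.0493). Of 22 p53 targets, 7 were higher and 2 lower (adjusted p = 0.0872, and 0.0457 without A1G replicate 3), among them Eda2r (7.39). Meningeal fibroblast markers had 2 higher and 8 lower of 19 (adjusted p = 0.0954, and 0.0407 without Ptch1 replicate 1). Erythrocyte markers had 3 lower of 5 (adjusted p = 0.0563, 0.0489 without cerebellum replicate 1 and 0.0289 without cerebellum replicate 2), and a replicate block also called them. Ependymal markers had 4 lower of 6 (0.163) and choroid plexus markers 1 lower of 6 (0.657). Pericyte markers had 5 lower of 12 (0.290), hypoxia genes 1 higher and 7 lower of 18 (0.290), immediate early and heat shock genes 3 higher and 6 lower of 20 (0.533), and Notch genes 6 higher and 3 lower of 18 (0.495). Oligodendrocyte precursor markers had 4 higher and 3 lower of 13 (0.891), with a median of -0.29 but a mean of 0.08 and an upward test. WNT targets had 2 higher and 2 lower of 10 (0.891, median -0.43, mean -0.10, test upward) and interferon-stimulated genes 3 higher and 2 lower of 18 (0.904, median -0.28, mean 0.05, test upward). T and NK cell markers had 0 of 3 past the test (0.891, median -0.63, mean 0.08, test upward) and neutrophil markers 0 of 4 (0.891). Of 7 abundant non-polyadenylated RNAs 1 was higher and 1 lower (0.962), and of 5 sex-linked genes 4 Y-linked genes were higher (0.533). Of these, Eif2s3y had no fragment in cerebellum and lost its call without A1G replicate 2 (adjusted p = 0.0826) or any 1 cerebellum library (0.0527 to 0.0620), and the other 3 also lost theirs without A1G replicate 2. These Y-linked genes were expressed mainly in A1G replicate 2 and Ptch1 replicates 1 and 2, so their rise followed the sex of the libraries, which the labels do not give.

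The last comparison asked whether the tumour kinds departed from cerebellum in the same genes. A1G tumours differed in 4650 genes, 2336 higher and 2314 lower, and Ptch1 tumours in 5729 genes, 2898 higher and 2831 lower. Of these, 2035 genes were higher in both kinds and 2012 lower in both, where independent lists would share 472 and 457, and 0 genes went opposite ways. The same 3 cerebellum libraries served each comparison, and in 20 simulations of shared controls without any effect 0 genes were called in both. Those simulations held no changed gene, so they do not show how far shared libraries enlarge the overlap of genes that do change. Across 10533 genes at 10 CPM or more the log2 changes had a Pearson r of 0.951, against 0.494 in the simulations, and genes are not independent replicates. Their covariance was 3.09, against 0.103 in the simulations. Ccnd2 changed by 6.87 in A1G and 7.30 in Ptch1 tumours, Atoh1 by 5.63 and 5.23, and Gli1 by 3.64 and 4.04. Calb1 changed by -5.27 in A1G and -9.08 in Ptch1 tumours, and Arhgef33 by -4.76 and -9.18, so these genes lay off the common trend. The 603 genes called in A1G tumours alone and the 1682 called in Ptch1 tumours alone are not shown to differ between the kinds, since the direct test called Calb1 and Arhgef33 only.

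**Figure D4:**
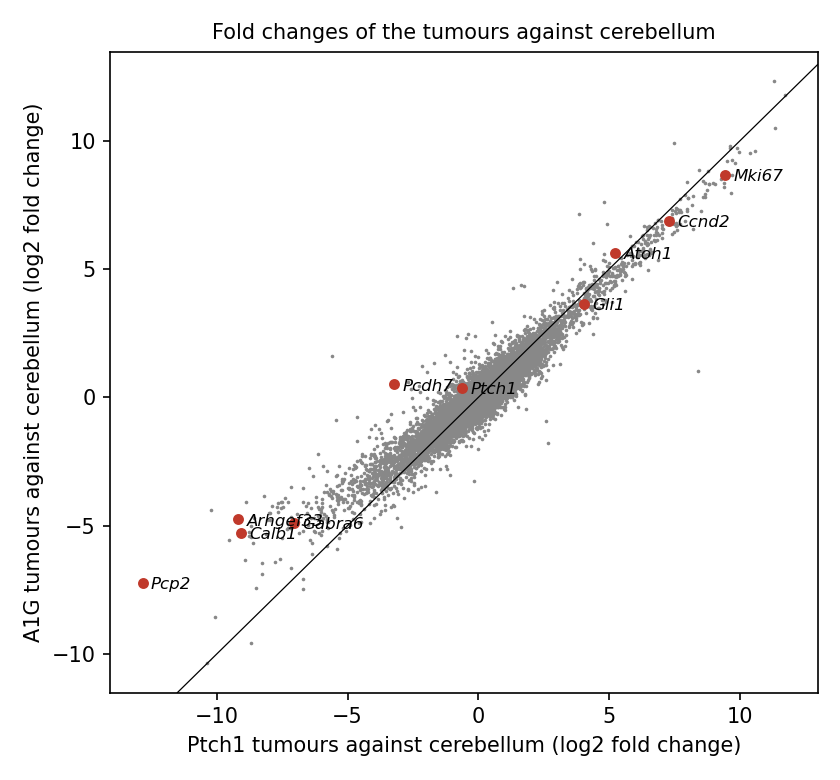
Log2 fold change of A1G tumours against cerebellum, plotted against that of Ptch1 tumours, for the 10533 genes at 10 CPM or more on average, with a line where the axes are equal and named genes in red. Most genes lay near the line, while Calb1, Arhgef33, Pcp2 and Pcdh7 lay above it.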

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

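Tests chosen only after their result was seen were the cell cycle change without A1G replicate 2, the share of cerebellar tissue under other choices of marker genes, the correlations over protein-coding genes alone and the shuffling of genes over chromosomes. The other tests of this part were set before their result was seen. The bound for the cell cycle change was tightened after its value was seen, by also asking that the list means of the tumour kinds not overlap, which moved that explanation from excluded to open. Calb1 and Arhgef33 passed edgeR's test between the tumour kinds, with differences of 3.81 and 4.42 on the log2 scale. A difference in distance from cerebellum is the same comparison, since the cerebellum level cancels. With 10 ways of dividing the 6 tumour libraries into groups of 3, the divisions are too few for a share under 0.05. The real division gave 2 genes, and 4 of the 10 divisions, the real one included, gave at least as many. The highest of the others gave 4. The count of 2 genes therefore does not set the real division apart from the others. For tumours against cerebellum the divisions argue against chance as the source. The real division gave 5852 genes in a fit of 2 groups and the highest of the others 4, with the real division the 1 that reached that count among 84. Every other division mixed tumour and cerebellum libraries within a group, which widens the spread and by itself lowers its count. The divisions do not address strain, which coincides with tissue in part. For A1G tumours against cerebellum the real division gave 4650 genes and the highest other 0, and for Ptch1 tumours 5729 and 0, with 10 divisions each, which are too few for a share under 0.05.

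Markers of mature cerebellar cells leaned higher and cell cycle genes lower in A1G than in Ptch1 tumours by limma's camera at its preset correlation, which 0 lists kept with an estimated correlation (adjusted p = 0.548 for the cell cycle genes), and adult cerebellar tissue left in the A1G samples is a candidate explanation. The share of such tissue that would account for the marker genes had a median of 2.64% (95% bootstrap interval 2.25 to 3.70) over the 53 of 72 list members with at least 20 CPM in cerebellum and 8 times the Ptch1 level, a choice that uses the Ptch1 level of the share itself, and of 2.56% (2.13 to 3.17) with the mean of all tumours in its place and 2.63% (2.13 to 3.70) over 71 members higher in cerebellum than in Ptch1 tumours, while dilution of the cell cycle genes by their median change would need 30.4%, so the tables argue against dilution for that part. Whether A1G replicate 2 alone lowered the cell cycle genes stays open, since without it their median log2 was -0.35 (adjusted p = 0.00305 at the preset correlation) while A1G replicate 1 had a list mean of 6.77 against 6.68 in Ptch1 replicate 3. For the markers the question stays open, since the list medians of the share ran from 2.18% for Purkinje cells to 5.49% for interneurons, and their ratio of 2.52 (1.72 to 4.94) neither requires nor excludes a common admixture. Of the genes named as higher in A1G, Calb1 was at 2.4002%, Arhgef33 at 3.59%, Rasgrf1 at 4.08%, Sema5a at 37.8% and Pcdh7 at 147%. The 95% intervals of the share and of the ratio came from resampling marker genes, not libraries, so they leave out the spread between tumours. By library, the 53 markers had a median of 3.89 to 7.34% of the cerebellum level in A1G and 1.13 to 3.38% in Ptch1 tumours. A difference by genotype remains open and untested.

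A1G replicate 2 stood apart from the other tumour libraries, with a mean rank correlation of 0.898 with them against 0.925 to 0.935 for the other 5 libraries. The library held 1.55% small RNA, against 0.234 to 0.534% in the other tumour libraries, and 2.07% ribosomal RNA (Rn45s), against 0.542 to 1.09%. Its protein-coding share was 88.9%, against 90.5 to 93.2%. Over protein-coding genes alone, 13368 of the 14337 tested, the correlation was 0.896 and the library stayed lowest. That argues against the carried-over RNAs themselves as the source, but could not exclude an effect of the preparation on the other genes. Sequencing depth is argued against by the correlation with all libraries thinned to the same number of fragments, 0.895, where the library also stayed lowest. Transcript length and GC content explained 5.85% of the variance of its deviation, too little for a bias of that kind to be the source. The library also had the lowest Mki67 (620 CPM), Sfrp1 (128 CPM), Spop (9.98 CPM) and Bmp5 (0.624 CPM) and the highest Ptch1 (299.7 CPM), Foxf2 (212 CPM) and Trp53 (96.4 CPM) of the 6 tumour libraries, genes chosen after their values were seen. No biological explanation was tested, and a tumour that differs from its group stays open.

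The median gene of a chromosome shifted in single tumour libraries, in 6 of 114 pairs of autosome and library with a median of 0.2 or more in size on the log2 scale. These were chromosome 17 in Ptch1 replicate 2 (0.37) and A1G replicate 2 (0.28), chromosome 18 in A1G replicate 2 (0.35), chromosome 14 in Ptch1 replicate 1 (0.32), and chromosome 6 in Ptch1 replicate 3 (0.24) and A1G replicate 3 (-0.22). Chance among genes is argued against by a p of 0.0005, the smallest that 2000 shuffles of genes over chromosomes can give, and a part of the chromosome or a few genes, as the whole cause, by the movement of either side of the chromosome in 6 of 6 shifts, though chromosome 6 in Ptch1 replicate 3 moved unevenly, by 0.10 on one side and 0.40 on the other. Transcript length, GC content and expression level are argued against because 6 of 6 shifts kept most of their size after a running-median correction for these. Gains or losses of chromosome copies are a candidate explanation that stays open, since no DNA data were analysed here. A gain to 3 copies in every cell would give 0.58 against libraries with 2 copies. The shifts, however, were taken against the median of the 6 tumour libraries, which a change in some of them also moves. On chromosome 17 the tumour libraries other than the raised pair lay at -0.15 to -0.05. The sizes of the shifts are therefore not directly comparable with 0.58.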

How the results depend on the processing

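The alternatives added after seeing the data were DESeq2, edgeR's own count filter, the robust test and protein-coding genes only. Limma on log2(FPKM + 1), planned as the main test, became an alternative when edgeR took its place. For single genes, the fit of only the groups compared, the fit without dispersion trend and voom with array weights were also added. For gene lists against cerebellum, median-of-ratios scaling was added. The counts against cerebellum stayed within 1.5 times their value under all 23 alternatives, from 4624 to 7960 genes for all tumours, 3376 to 6005 for A1G, 4424 to 7600 for Ptch1 and 3016 to 5323 shared. The 2 genes between A1G and Ptch1 tumours became 81 without a filter on low values and 163 with DESeq2. They became 0 with only the groups compared, 0 without a dispersion trend, 0 with quantile normalization, 0 with voom and array weights and 0 with limma on log2(FPKM + 1), where 1308, 1453, 1164, 1848 and 1391 genes had an unadjusted p under 0.05. Leaving out 1 library gave 0 to 4 genes, with 0 without Ptch1 replicate 2 (1266 at an unadjusted p under 0.05), 3 without Ptch1 replicate 1, and 4 without A1G replicate 1, 2 or 3 or Ptch1 replicate 3. The cause was not tested. Adjusted p ranged from 8.9e-12 to 0.449 for Calb1 and from 4.7e-10 to 0.449 for Arhgef33. Of the 9 lists called between the tumour kinds, 0 passed with an estimated correlation and 0 with fry. Of the 13 against cerebellum, 5 passed with an estimated correlation, and fry, which asks another question, called 20. Of 125 named genes past the test against cerebellum, 105 kept their call and direction under every alternative run and 20 lost it in some. Hba-a2, an alpha-globin gene, reversed, with -7.37 in the full fit and 0.54 without cerebellum replicate 3, the library with 292.5 CPM where the other cerebellum libraries had 0.525 and 0.304; leaving out other libraries gave down to -9.08. Replicate numbers were not treated as pairs, though 5 of the 9 libraries correlated best with one of their own number. The highest correlation of any pair, 0.24, was between libraries of different numbers. A replicate block gave 2, 5891, 4456 and 5593 genes in the 4 comparisons. The block called 9 lists between the tumour kinds and 14 against cerebellum, with the erythrocyte markers added. Depth limits genes near the floor of 3 fragments, and 2-fold changes between tumour kinds were recovered in 7.46% of simulated cases at a mean of 10 CPM or more over all 9 libraries.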

Other observations

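Xist, the RNA that silences an X chromosome, was at 2258 and 4213 CPM in A1G replicates 1 and 3 and at 482, 645 and 1018 CPM in the cerebellum libraries, against 3.74 CPM in A1G replicate 2 and 0, 1.57 and 46.4 CPM in the Ptch1 libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in A1G replicate 2 and Ptch1 replicates 1 and 2, with Ddx3y at 53.3, 78.3 and 80.8 CPM there and at up to 1.11 CPM in any other library. Ptch1 replicate 3 had 0 CPM of these 4 genes together with the 46.4 CPM of Xist. The labels used here give no sex. By these genes sex differed between libraries and was not balanced between the groups, so it could not be separated from the group in the Xist and Y-linked differences. These genes, and those that follow, were chosen after their values were seen.

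Cdkn2a, a tumour suppressor gene (chromosome 4, 89274471 to 89294653), was at 38.7 CPM in Ptch1 replicate 3 and at 2.47 to 13.1 CPM in the other 5 tumour libraries, and it had no fragment in cerebellum. Trp53, which encodes p53 (chromosome 11, 69580359 to 69591873), was at 96.4 CPM in A1G replicate 2 and at 25.4 to 39.99 CPM in the other 5. Over 53 of 72 mature cerebellar markers, kept for a cerebellum level of at least 8 times the Ptch1 tumour mean, which by itself holds the Ptch1 values down, the median was 3.89%, 3.997% and 7.34% of the cerebellum level in A1G replicates 1 to 3, and 3.38%, 1.13% and 2.66% in the Ptch1 replicates.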
